A study of Mus musculus with 20 samples.

How the data were processed

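Epidermis was taken from mice with whole-body deletion of Acly and Acss2 and from wild type mice, 12 or 21 days after tamoxifen, per the labels' protocols. RNA was purified with the RNeasy Mini kit, polyadenylated RNA was selected with the NEBNext Poly(A) module, and directional libraries were made with the NEBNext Ultra Directional kit and read from 1 end, per the labels' protocols. Per the submitters' processing notes, the tools were STAR and DESeq2 and the genome was mouse GRCm38 (mm10). Versions of STAR and DESeq2, the gene annotation and the read filters are not given in the sources used here. The deposited values are a signal per gene that the authors had divided by scaling factors, with DESeq2 by the name they gave the tables, each day apart. They are not raw counts.

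There are 2 deposited tables, for 12 and 21 days, each with 24972 genes and 1023603 empty lines. A library's commonest low value was taken as the value of 1 read. Values up to 3.5 such steps lay within 0.1 of a whole multiple in 85.3 to 96.1% of cases, so whole reads were not recovered and no test that needs counts was run. The estimated depth of a library, 13.4 to 28.4 M reads (M for 1e+06), is the sum of its values divided by that step. Each table had 26 gene symbols that spreadsheet software had turned into dates, 2 of them used for more than 1 gene. These genes stayed in the fits without a name. Of the symbols 24407 matched the RefSeq annotation of GRCm38.p6, and 24860 did once synonyms were allowed. No mitochondrial genes were in the tables.

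Sex was taken from the sample titles, because 1 label gave male for all samples. Labels of genotype, day and sex were set down before the data were examined, together with the tests and gene lists. That design named quasi-likelihood tests on counts as the first choice, with the test the unit needs where there were no raw counts. Since the values are the authors' normalised signal, genes were fitted with limma (with a trend of variance on level) on log2(value + 1). The design also allowed a comparison of the days only for raw counts. It was run here as a difference of fold changes, each taken within its own table, and the departure is named because the tables were normalised apart. The planned filter by counts was replaced by a value of at least 10 in as many libraries as the smallest group has. That number was kept when a library was left out, so a gene high in 1 genotype only could then leave the fit.

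KO against WT at 12 days in both sexes came from a fit of genotype with a term for sex. A fit of the 4 groups of genotype and sex gave KO against WT in females and in males, and the difference between the sexes. At 21 days KO was compared with WT in males. The difference between days came from a fit of the 4 male groups of both tables. P-values were adjusted with Benjamini-Hochberg within each comparison, and genes below 0.05 were called. Fold changes are KO over WT on the log2 scale. On simulated data with the group sizes of these comparisons and 200 changed genes, the fits recovered 60.6% of 1.5-fold, 86.6% of 2-fold and 98.5% of 4-fold changes at 12 days in both sexes, with 10 unchanged genes among 183 calls. At 21 days they recovered 47.7%, 77.3% and 98.5%. For the difference between sexes the shares were 8.96%, 47% and 74.2%, and for the difference between days 17.9%, 62.7% and 86.2%. A further small list of genes was raised 1.5-fold in the same simulations. The adjusted threshold depends on how many genes change, and in the real fit of 21 days 9557 of 13588 were called. No library standing apart from its group was simulated. The shares thus describe the simulated setting and not the sensitivity in the real data.

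The 37 gene lists were tested with limma's camera at its preset correlation of 0.01 and with the correlation estimated from each list, and with fry. Lists with fewer than 3 measured members were not tested, and adjustment was over the lists of a comparison. Counts adjusted over the list alone use the p-values of its own members. The sexes and the days were compared by called genes with Fisher's exact test. Regroupings of the libraries exchanged genotype labels (within sex at 12 days) for KO against WT, sexes within genotype for the difference between sexes, and days within genotype for the difference between days, with the fit repeated for each.

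Genes named in the text were drawn by a rule. For both main comparisons these were Acly and Acss2, and the 10 largest rises and 10 largest falls among called genes with a mean CPM (value per library total of 1e+06) of at least 5 and every KO library on the same side of the WT mean of its sex. From each list came up to 4 members with the smallest p and the member with the highest mean. For each difference between sexes or days the 5 smallest p-values were taken, and the sex genes were added. Unnamed and predicted genes were left out. Not all of the genes so drawn are printed.

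Gene counts of each comparison and named genes were run again with other normalisations, filters and weights and without each library in turn. Lists were run with an estimated correlation, with fry and without each library in turn in every comparison, and with the other settings only at 12 days in both sexes and at 21 days. A fold of 1.5 was tested only in those 2 comparisons. Tools were R 4.3.3, limma 3.58.1, data.table (1.17.8) and matplotlib 3.10.9, and the fit and list test were tested on simulated data.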

Results

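The series measured RNA in the epidermis of mice in which Acly and Acss2 had been deleted throughout the body with a tamoxifen-activated Cre recombinase (UBC-CreERT2). Acly encodes ATP citrate lyase, which makes cytosolic acetyl-CoA from citrate, and Acss2 encodes the enzyme that makes it from acetate. The question was how acetyl-CoA metabolism bears on the way lipids are divided between adipose tissue and skin. Epidermis was taken 12 or 21 days after tamoxifen from mice with the deletion (KO) and from wild type mice (WT). At 12 days each genotype had 3 females and 3 males, and at 21 days each had 4 males, which made 20 libraries. Whether the WT mice carried the Cre transgene is not given in the sources used here. One label gave male for every sample, so sex was taken from the sample titles. The 6 libraries titled female had Xist values of 11590 to 16810 and a sum of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) of 0 to 6.042. The 14 titled male had Xist values of 0 to 25.95 and Y-linked sums of 3721 to 5563.

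The deposited values of a library, normalised by the authors within each day, summed to 17.8 to 23 M (M for 1e+06), and the estimated depth was 13.4 to 28.4 M reads. At 21 days the KO libraries were the deeper ones, with 22.5 to 28.4 M estimated reads against 16 to 17 M in WT. Their 10 highest genes also took a larger share of the values, 10.3 to 11.4% against 7.14 to 8.42%. The labels do not say more of the samples than that mice were harvested, so p-values measure the spread between these samples. Fold changes are on the log2(value + 1) scale, each with its standard error (SE), and were tested with limma with Benjamini-Hochberg adjustment. Gene values are means ± SD of the authors' normalised values.

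Acly fell at both days and Acss2 fell at 12 days. At 12 days Acly (chromosome 11, 100476352 to 100528000, GRCm38) went from 9133 ± 1870 in WT to 3360 ± 408 in KO (SD, n = 6 each), and the highest KO library, at 4136, lay below the lowest WT library, at 6431. The log2 fold change was -1.42 (SE 0.13, limma adjusted p = 0.000122). Acss2 (chromosome 2, 155518043 to 155562743) went from 331.4 ± 92.6 to 137 ± 36.5 (n = 6 each), with KO libraries at 108.4 to 205.6 and WT libraries at 246.3 to 489.8. Its log2 fold change was -1.26 (SE 0.18, limma adjusted p = 0.0017). At 21 days Acly went from 7867 ± 655 to 4958 ± 775 (n = 4 each), a log2 fold change of -0.68 (SE 0.12, limma adjusted p = 0.000532). Acss2 was at 329 ± 30.4 in WT and 357.6 ± 34.6 in KO (n = 4 each) at 21 days, a difference of 0.12 (SE 0.10, limma adjusted p = 0.319), or -0.10 when the values were scaled to equal totals. These are totals over each gene, and the deleted exons are not given in the sources used here, so the deletion itself was not measured.

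**Figure D1:**
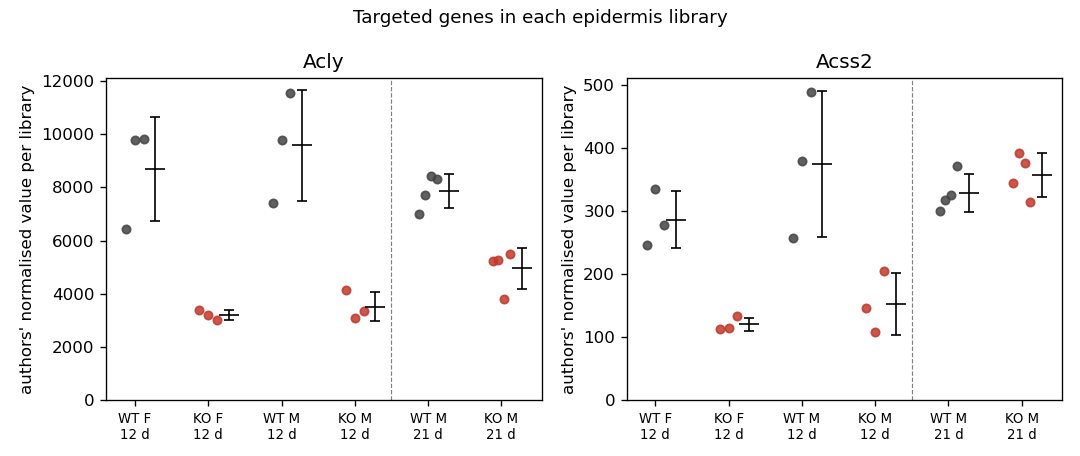
The authors' normalised values of Acly and Acss2 (linear vertical axes from 0) in each library, by genotype, sex (F, M) and day, with the group mean and SD (n = 3 per group at 12 days and 4 at 21 days). Acly was 3008 to 4136 in the KO libraries of 12 days and 3805 to 5488 in those of 21 days, and Acss2 lay at 315.1 to 392.9 in the KO libraries of 21 days; the days were normalised separately.

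At 12 days the genes named by the rule rose by more than they fell. With a mean CPM (value per library total of 1e+06) of at least 5, the largest rises included a stress keratin, alarmins of the epidermis and Cyp2g1. Krt6b, a keratin of stressed and wounded epidermis, rose by 6.37 on the log2 scale (SE 1.08, limma adjusted p = 0.00549), from 63.22 ± 51.9 to 29720 ± 66000 (n = 6 each), with KO females at 398.8 to 4636 and KO males at 1651 to 164400. Its log2 fold change was 5.35 without KO male 2, the highest library of 12 days (SE 0.70, limma adjusted p = 0.00114). S100a9, an alarmin, rose by 5.76 (SE 0.79, limma adjusted p = 0.00147), and its partner S100a8 by 5.62 (SE 1.03), or by 5.01 and 4.73 without KO male 2. Other stress keratins moved less, with Krt17 at 1.18 (SE 0.21, limma adjusted p = 0.00749) and Krt6a, named here after its values were seen, at 0.43 (limma adjusted p = 0.652), or -0.00 without KO male 2 (adjusted p = 0.997). Krt16, also added after its values were seen, had 2.47 without KO male 2 (SE 0.36, limma adjusted p = 0.00208). Cyp2g1, a cytochrome P450, rose by 5.73 (SE 0.66), from 18.36 ± 21.5 to 736.4 ± 552. Esr1, estrogen receptor alpha, rose by 5.39 (SE 0.30, limma adjusted p = 4.76e-06), from 19.08 ± 8.63 to 802.6 ± 215, with the lowest KO library at 414.4 and the highest WT library at 29.73. CreERT2 carries a part of an estrogen receptor gene, so these reads may come from the transgene in place of the Esr1 gene. The cornified envelope precursor Sprr2g rose by 4.89 (SE 0.89), or 4.12 without KO male 2. Sprr2g belongs to a family of close copies, so its reads are uncertain. The largest falls were smaller. Igfbp3, which binds insulin-like growth factors, fell from 10700 ± 2030 to 3345 ± 1630, a log2 fold change of -1.83 (SE 0.25, limma adjusted p = 0.0015), and Pls1, an actin-bundling protein, had -1.63 (SE 0.28). All 6 KO libraries lay on the same side of the WT mean of their sex for each of these genes except Krt6a, which the rule did not name, and Krt16, which was not looked at for this.

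In all, 815 of 13927 genes tested changed at 12 days, 495 higher and 320 lower in KO. Changes of at least 2-fold were found for 378 of them, 327 higher and 51 lower. Without a single library the count was 451 (WT male 6), 449 (WT female 9), 499 (KO female 8) and 493 (KO male 12), and without KO male 2, the library farthest from the others, it was 894. It was 504 (240 higher, 264 lower) among genes with a mean CPM of at least 5, 1382 in 1 fit of all 20 libraries, 2259 with array weights and 93 when tested against a fold of 1.5.

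Genes of lipid metabolism changed little at 12 days outside a few enzymes. Of 37 gene lists fixed beforehand, 34 had at least 3 measured members at 12 days and 12 passed the camera test at its preset correlation of 0.01, all toward higher values in KO. None of these calls held with an estimated correlation between genes, at 12 or at 21 days. The ceramide and barrier lipid list was higher, with a median log2 fold change of 0.31 (camera adjusted p = 0.000362, adjusted p = 0.656 with an estimated correlation and 0.246 with fry). Of its 26 measured members 3 rose and none fell, and adjusted over the list alone 3 rose. They included Fa2h, a fatty acid 2-hydroxylase, at 1.37 (SE 0.26, limma adjusted p = 0.00954), from 503.6 ± 208 to 1323 ± 716. Cers4 and Cers2, also among them, each lost the call in 10 of 12 runs without 1 library (limma adjusted p up to 0.118 and 0.116). The triglyceride and lipid droplet list had a median of 0.31 (camera adjusted p = 0.00263, adjusted p = 0.19 with an estimated correlation), and 5 of its 17 members rose and 1 fell (6 and 1 adjusted over the list alone). Dgat1, an enzyme of the last step of triglyceride synthesis, rose by 0.34 (SE 0.07), and the lipid droplet protein Plin2 by 0.36 (SE 0.08), from 572.8 ± 51.2 to 735.4 ± 51.8.

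De novo lipogenesis genes did not pass, with none of 16 members past the threshold over all genes or adjusted over the list alone, and a median of 0.13 (camera adjusted p = 0.13). This depended on single libraries, since the list passed without WT male 11 (0.21, adjusted p = 0.0309) or KO male 5 (0.18, adjusted p = 0.0329) and had 0.25 with 1 member higher without KO male 2 (adjusted p = 0.0538). Scd1, the most abundant member, was at 10610 ± 2580 in WT and 11520 ± 2090 in KO (limma adjusted p = 0.735). The list of other acetyl-CoA supply (citrate and pyruvate enzymes and carriers) had none of 10 members past the threshold by either adjustment and a median of 0.03 (camera adjusted p = 0.82). Cholesterol synthesis genes had a median of 0.17 (camera adjusted p = 0.218), and 1 of 24 members rose by either adjustment. This was Dhcr24, which reduces desmosterol to cholesterol, at 0.79 (SE 0.16, limma adjusted p = 0.0125), from 3116 ± 605 to 5465 ± 1440. The cholesterol list passed without WT male 11 (0.26, adjusted p = 0.0309) or KO male 5 (0.26, adjusted p = 0.00216), and had 0.06 without KO male 2 (adjusted p = 0.904). LXR targets had none of 8 members past the threshold (1 lower adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.874). Fatty acid uptake genes had 1 member higher of 9 (2 higher and 1 lower adjusted over the list alone). Their median was -0.05, while the mean was 0.25 and the test pointed up (camera adjusted p = 0.874). Fatty acid oxidation and PPAR targets had 1 higher and 1 lower of 27, with a median of -0.01, a mean of 0.01 and a test pointing down (camera adjusted p = 0.388). The lower one was Cpt1a, which imports fatty acids into mitochondria, at -0.70 (limma adjusted p = 0.0219). Its call was lost without WT male 6, WT female 9, KO female 8 or KO male 12 (adjusted p up to 0.0598). The higher one, Acot1, lost its call in 10 of 12 runs without 1 library (limma adjusted p up to 0.0976).

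Sebaceous gland genes were higher at 12 days, with 6 of 14 members up and none down (10 adjusted over the list alone) and a median of 0.99 (camera adjusted p = 1.07e-07, adjusted p = 0.19 with an estimated correlation). Elovl3, a fatty acid elongase, rose by 2.00 (SE 0.23, limma adjusted p = 0.000514), from 162.8 ± 83 to 619.3 ± 249. Mgst1 rose by 1.08 (SE 0.11), Soat1, which esterifies cholesterol, by 1.17 (SE 0.22), and Far2, which makes fatty alcohols for waxes, by 1.09 (SE 0.23). Cornified envelope genes were also higher, with 4 of 25 members up (12 adjusted over the list alone) and a median of 0.75 (camera adjusted p = 2.95e-06, adjusted p = 0.362 with an estimated correlation). Lce1g rose by 2.87 (SE 0.41, limma adjusted p = 0.00213), from 152.1 ± 89.7 to 1080 ± 586, though reads of the Lce1 copies are uncertain. Basal keratinocyte genes (none of 12, median 0.04, camera adjusted p = 0.82) and suprabasal keratinocyte genes (none of 17, median 0.06, camera adjusted p = 0.76) did not pass by either adjustment. Hair follicle stem cell genes had none of 10 past the threshold (1 higher and 2 lower adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.76). Krt15, their most abundant member, was at 182900 ± 31200 in WT and 166700 ± 27000 in KO. Among growing hair shaft genes 1 of 14 fell (1 higher and 2 lower adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.82). This was Foxn1, a transcription factor of hair differentiation, at -0.81 (SE 0.17, limma adjusted p = 0.0169).

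The interferon response genes were higher in KO at 12 days. Of 31 members 22 rose and none fell (30 rose adjusted over the list alone), with a median of 1.97 (camera adjusted p = 2.5e-26, adjusted p = 0.19 with an estimated correlation). Oas2, which senses double-stranded RNA, rose by 2.80 (SE 0.35, limma adjusted p = 0.000867), from 44.04 ± 12.8 to 344.9 ± 181. Oas1g rose by 3.04 (SE 0.39) and the antiviral gene Rsad2 by 3.93 (SE 0.52), from 7.628 ± 4.03 to 151.9 ± 111. The barrier stress list of keratins, alarmins and small proline-rich proteins had 13 of 23 members higher and none lower (21 adjusted over the list alone), with a median of 3.45 (camera adjusted p = 4.02e-16, adjusted p = 0.326 with an estimated correlation). Its mean score over members was 13.11 in KO male 2, 6.195 to 8.869 in the other KO libraries and 4.568 to 6.009 in WT. Inflammatory mediators had 10 of 15 higher and none lower (14 adjusted over the list alone), with a median of 1.69 (camera adjusted p = 1.35e-12, adjusted p = 0.19 with an estimated correlation). Ccl20, a chemokine, rose by 3.21 (SE 0.28, limma adjusted p = 7.86e-05), from 70.12 ± 26.6 to 707.7 ± 464, and Ptgs2, a cyclooxygenase, by 1.90 (SE 0.27). Proliferation genes had 7 of 30 higher and none lower (22 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 1.04e-11, adjusted p = 0.362 with an estimated correlation). Without KO male 2 the medians were 2.00 for interferon, 2.71 for barrier stress (3.53 with it, over the 20 members that then passed the filter) and 0.76 for proliferation genes, and each list still passed. With the CPM filter the proliferation median was 0.66.

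Among stress and energy pathways at 12 days, p53 targets had 4 of 10 members higher and none lower (5 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 1.9e-05, adjusted p = 0.19 with an estimated correlation). Bax, which promotes cell death, rose by 0.58 (SE 0.07, limma adjusted p = 0.000523), from 379.4 ± 14.1 to 569.6 ± 40.6 and Ccng1, a cyclin, by 0.74 (SE 0.11). Integrated stress response genes had 3 of 17 higher by either adjustment and a median of 0.19 (camera adjusted p = 0.00344, adjusted p = 0.362 with an estimated correlation). They included Cth, a cysteine synthesis enzyme, at 1.38 (SE 0.25). Slc7a11 had a larger log2 fold change, 2.52, or 1.82 without KO male 2, but lost its call in 10 of 12 runs without 1 library. Chaperones of the endoplasmic reticulum (ER) had 1 of 14 higher (2 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.00169, adjusted p = 0.49 with an estimated correlation and 0.0957 with fry). Glycolysis genes had 2 of 18 higher (4 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.00444, adjusted p = 0.656 with an estimated correlation and 0.21 with fry), led by Pfkl at 0.78 (SE 0.13). The medians were 0.14 for glycolysis (adjusted p = 0.0173) and 0.16 for ER chaperones (adjusted p = 0.00486) without KO male 2. NRF2 targets (2 of 17 higher by either adjustment, median 0.18, camera adjusted p = 0.103) did not pass. Nor did oxidative phosphorylation genes (none of 20, median 0.11, camera adjusted p = 0.0978) or lysine acetyltransferases and deacetylases (none of 17, median -0.06, camera adjusted p = 0.21), by either adjustment. Oxidative phosphorylation genes passed with the CPM filter (adjusted p = 0.0241) and without WT female 7 (adjusted p = 0.0405), WT male 11 (adjusted p = 0.0309), KO male 5 (adjusted p = 0.0314) or KO male 12 (adjusted p = 0.0172), and had 0.02 without KO male 2 (adjusted p = 0.852). NRF2 targets passed with the CPM filter (adjusted p = 0.0297) and without KO male 5 (0.29, adjusted p = 0.0254).

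Markers of other cell types passed camera in no list at 12 days, and with fry the endothelium list passed (adjusted p = 0.0477). The medians were -0.08 for dermal fibroblasts (none of 9), -0.02 for skeletal muscle (none of 3), 0.72 for endothelium (none of 3, with 1 higher adjusted over the list alone; 0.28 without KO male 2), 0.28 for melanocytes (none of 3; -0.05 without KO male 2) and -0.36 for red blood cells (none of 3; -0.12 without KO male 2). The immune lists had medians of 0.08 for Langerhans and dendritic cells (1 of 9 higher), 0.14 for T cells (none of 11, mean -0.03, test pointing down) and -0.04 for macrophages (none of 6, mean 0.08, test pointing up). Neutrophil genes had a median of -0.33 (-0.11 without KO male 2) but a mean of 0.83 and a test pointing up (1 of 3 higher). Camera adjusted p-values of these lists lay between 0.208 for endothelium and 0.941 for fibroblasts and muscle. Adipocyte, mast cell and Schwann cell lists had fewer than 3 measured members at 12 days.

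Within each sex at 12 days, Acly fell in females by 1.42 (log2 -1.42, SE 0.20, limma adjusted p = 0.0107) and in males to the same degree (log2 -1.43, SE 0.20, limma adjusted p = 0.00669), each with n = 3 against 3. The female call was lost without WT female 9 (adjusted p = 0.065) or KO female 4 (adjusted p = 0.0514), 8 (adjusted p = 0.0644) or 10 (adjusted p = 0.0588), and the male call in the 6 male libraries alone (adjusted p = 0.0688). Acss2 had -1.24 in females (SE 0.26, limma adjusted p = 0.0709) and -1.29 in males (SE 0.26, limma adjusted p = 0.0418). The male Acss2 call was lost in the 6 male libraries alone (adjusted p = 0.259), with vooma (adjusted p = 0.0637), the CPM filter (adjusted p = 0.0572) and no trend (adjusted p = 0.057). It held without WT male 3 or KO male 12 and was lost without WT female 1 (0.0579), 7 (0.0616) or 9 (0.0665), WT male 6 (0.158) or 11 (0.127), KO female 4 (0.0607), 8 (0.0681) or 10 (0.0643), or KO male 2 (0.0907) or 5 (0.0675). In females Acss2 passed under total scaling (adjusted p = 0.0391), with array weights (adjusted p = 0.00402), in the 6 female libraries alone (adjusted p = 0.0173) and without WT male 3 (adjusted p = 0.0369). Interferon genes were higher in both sexes, with a median of 1.81 in females (3 of 31 higher, 24 adjusted over the list alone) and 2.08 in males (7 of 31 higher, 23 adjusted over the list alone). Sebaceous gland genes had medians of 1.15 and 0.90, with 2 of 14 higher in each sex (8 and 3 adjusted over the list alone). Barrier stress genes had medians of 2.25 in females (none of 23 past the threshold, 9 adjusted over the list alone) and 5.06 in males (6 higher, 22 adjusted over the list alone). In females and males the camera adjusted p-values were 6.46e-26 and 3.34e-23 for interferon, 4.98e-10 and 6.89e-05 for sebaceous gland, and 6.44e-10 and 4.07e-21 for barrier stress genes. Inflammatory mediators (medians 1.37 and 2.03), proliferation (0.46 and 1.46), p53 targets (0.39 and 0.27), ceramide (0.33 and 0.40), triglyceride (0.27 and 0.35), cornified envelope (0.49 and 0.75) and ER chaperone genes (0.24 and 0.28) also passed in each sex (largest camera adjusted p = 0.00655). Glycolysis (0.47, camera adjusted p = 8.5e-06), integrated stress response (0.39, camera adjusted p = 0.000289) and oxidative phosphorylation genes (0.17, camera adjusted p = 0.0125) passed in males, with 0.09, 0.09 and 0.04 in females. Without KO male 2 the ER chaperone (0.12, adjusted p = 0.168) and oxidative phosphorylation (0.00, adjusted p = 0.963) calls in males ended, and male medians were 3.18 for barrier stress (4.62 with it, over the same 20 members), 0.95 for proliferation, 0.26 for glycolysis and 0.46 for p53 targets. The male calls of ceramide (0.03, adjusted p = 0.789), ER chaperone (adjusted p = 0.264) and oxidative phosphorylation genes (0.08, adjusted p = 0.404) also ended without WT male 3, where cornified envelope genes had 0.48, and that of triglyceride genes without KO male 12 (adjusted p = 0.0918). In females the ceramide (0.08, adjusted p = 0.52) and ER chaperone (0.17, adjusted p = 0.205) calls ended without WT female 1. The male medians were also 0.45 for ER chaperones without KO male 5, 0.26 for oxidative phosphorylation and 0.16 for p53 targets without KO male 12, and 0.22 for the integrated stress response without WT male 11, and the female ones 0.31 for cornified envelope genes and 0.25 for p53 targets without WT female 1. No list passed with an estimated correlation (smallest adjusted p = 0.239 in females and 0.168 in males). With fry none passed in females (smallest adjusted p = 0.072) and only inflammatory mediators did in males (adjusted p = 0.00749).

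In females 93 genes changed (77 higher, 16 lower) and in males 180 (141 higher, 39 lower), of 13927 tested. The sexes shared 55 genes higher and 9 lower, where lists independent of each other would share 0.78 and 0.0448, and across genes their fold changes had r = 0.688 and rho = 0.576 (genes are not independent replicates). Both sexes took the spread of each gene from the same fit, so genes of low spread tend to be called in both. The calls were thus not independent by design, and the numbers for independent lists are too low a measure of chance. The female count without 1 library was 25 (WT female 1), 43 (WT female 7), 16 (WT female 9), 18 (KO female 4), 18 (KO female 8), 22 (KO female 10), 55 (WT male 6) and 142 (KO male 2), and 190 from the 6 female libraries alone. The male count was 38 (WT male 6), 65 (WT male 11), 103 (KO male 2), 289 (KO male 5), 80 (KO male 12), 115 (WT female 1), 110 (WT female 7), 103 (WT female 9), 100 (KO female 8) and 112 (KO female 10), and 22 from the 6 male libraries alone.

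The sexes differed in their response for 1 gene and for 7 of the lists fixed beforehand. Barrier stress genes rose more in males, by a median of 2.31 (camera adjusted p = 3.48e-10), proliferation genes by 0.90 (camera adjusted p = 2.24e-14), inflammatory mediators by 0.55 (camera adjusted p = 6.09e-05), glycolysis genes by 0.37 (camera adjusted p = 9.96e-08), integrated stress response genes by 0.19 (camera adjusted p = 0.0135) and oxidative phosphorylation genes by 0.13 (camera adjusted p = 0.0223). Sebaceous gland genes rose less in males, with a median of -0.30 (camera adjusted p = 0.0433). With an estimated correlation none passed, the smallest adjusted p = 0.712, and with fry none did (adjusted p = 0.998). Without KO male 2 only the inflammatory (0.12, adjusted p = 0.0221), proliferation (0.41, adjusted p = 1.5e-06) and glycolysis (0.17, adjusted p = 0.000658) calls remained of these 7. Barrier stress then had 0.70 (adjusted p = 0.116; 2.22 with that library over the same 20 members), sebaceous gland -0.19 (adjusted p = 0.136), integrated stress response 0.08 (adjusted p = 0.217) and oxidative phosphorylation -0.01 (adjusted p = 0.633), and the interferon list passed with 0.55 (adjusted p = 5.26e-06). The integrated stress response call was also lost without WT female 7 (0.06, adjusted p = 0.266) or KO female 10 (adjusted p = 0.0732), and oxidative phosphorylation without WT female 7 (0.07, adjusted p = 0.229) or 9 (adjusted p = 0.0547), WT male 3 (0.03, adjusted p = 0.633) or KO female 10 (adjusted p = 0.115). The sebaceous gland call was also lost without WT female 9 (-0.10, adjusted p = 0.777), WT male 3 (adjusted p = 0.352) or 11 (adjusted p = 0.0703), KO female 8 (-0.14, adjusted p = 0.302) or KO male 5 (-0.05, adjusted p = 0.434). Medians of calls that held reached 0.85 for inflammatory mediators (WT male 6), 0.32 for the integrated stress response (KO male 5), 0.22 for oxidative phosphorylation (KO male 12) and -0.54 for sebaceous gland genes (KO male 12). The 1 gene was Mfrp, at 7.36 (SE 0.56, limma adjusted p = 0.000443). It was listed at 0 in all 3 WT males of 12 days and at 59.5 to 230.1 in the other groups of that day, and it overlaps C1qtnf5, so its reads are uncertain. At an unadjusted p under 0.05 there were 167 genes of 13927. The next by p were Cyp2g1 (3.72), Hist1h2ao (5.38), Hmgcll1 (1.48) and Esr1 (1.63), each with limma adjusted p = 1.

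At 21 days most of the transcriptome differed between KO and WT males. The largest rises, of about 10 on the log2 scale, were in small proline-rich proteins, alarmins and the stress keratin Krt6b, among others. Krt6b went from 263.6 ± 281 to 190500 ± 30000 (SD, n = 4 each), a log2 fold change of 10.19 (SE 0.70, limma adjusted p = 8.87e-07). S100a9 went from 79.94 ± 71.8 to 66560 ± 13900, at 10.39 (SE 0.81, limma adjusted p = 1.93e-06). Sprr2b (10.61, SE 0.43), Sprr2e (10.54, SE 0.76) and Lce3b (10.20, SE 0.53) were among the 5 largest rises, and as members of families of close copies their reads are uncertain. The largest falls were in B4galnt2, a glycosyltransferase (-7.59, SE 0.40), and in Mrgprb2, a receptor known from mast cells, which went from 566.8 ± 50.4 to 2.106 ± 0.844 (-7.55, SE 0.23, limma adjusted p = 1.01e-08). Gabrp, a GABA receptor subunit, had -7.32 (SE 0.24) and the peptide hormone gene Pyy -7.29 (SE 0.50). B4galnt2, Mrgprb2, Gabrp and Pyy passed the filter only through their WT libraries, so for them a lower value in KO was fixed in advance. Igfbp3 fell from 7570 ± 2060 to 128 ± 39.4 (-5.88, SE 0.24, limma adjusted p = 4.31e-08). In total 9557 of 13588 genes changed, 4857 higher and 4700 lower, and 3854 by at least 2-fold (1779 higher, 2075 lower). Scaling to equal totals shifted the median of all genes by -0.22 and gave 9599 calls, 3564 higher and 6035 lower, so that 37.1% in place of 50.8% of the calls were higher. Tested against a fold of 1.5, 4051 genes passed (1967 higher, 2084 lower).

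Lipid synthesis genes rose at 21 days. Counts of members adjusted over the list alone were the same as over all genes at 21 days, except where both are given. Cholesterol synthesis genes had 22 of 24 members higher and none lower, with a median of 1.26 (camera adjusted p = 1.11e-07, adjusted p = 0.494 with an estimated correlation). Idi1, of the isoprenoid part of the pathway, rose by 2.92 (SE 0.14, limma adjusted p = 8.83e-08), from 2725 ± 445 to 20660 ± 3140, and Acat2, which joins acetyl-CoA units, by 2.90 (SE 0.13), from 793.8 ± 122 to 5907 ± 808. De novo lipogenesis genes had 11 of 16 higher and 1 lower (11 and 2 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 0.00782, adjusted p = 0.494 with an estimated correlation). Fasn, fatty acid synthase, rose by 1.37 (SE 0.10, limma adjusted p = 1.03e-06), from 6841 ± 384 to 17760 ± 2260, and the desaturase Scd2 by 2.11 (SE 0.14). Other acetyl-CoA supply genes had 9 of 10 higher, with a median of 0.62 (camera adjusted p = 0.00237, adjusted p = 0.21 with an estimated correlation). They included the citrate carrier Slc25a1 (0.94, SE 0.06) and Dlat, a subunit of pyruvate dehydrogenase (1.07, SE 0.07). Ceramide and barrier lipid genes had 21 of 26 higher and 2 lower, with a median of 1.17 (camera adjusted p = 0.000137, adjusted p = 0.494 with an estimated correlation). Elovl4, which makes very long chain fatty acids, rose by 2.09 (SE 0.19), from 11020 ± 2940 to 45920 ± 6560. Triglyceride and lipid droplet genes had 12 of 18 higher and 2 lower, with a median of 0.95 (camera adjusted p = 0.0154, adjusted p = 0.494 with an estimated correlation). The median was 0.62 with no filter. Dgat1 rose by 1.15 (SE 0.12), and Pnpla2, a triglyceride lipase, fell with a log2 fold change of -0.90 (SE 0.09).

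Fatty acid uptake genes went both ways at 21 days, with 5 of 9 higher and 3 lower and a median of 1.21 (camera adjusted p = 0.409). Fabp5, the fatty acid binding protein of epidermis, rose by 4.29 (SE 0.20, limma adjusted p = 9.98e-08), from 4149 ± 1350 to 78430 ± 7230. Fatty acid oxidation and PPAR targets had 14 of 27 higher and 3 lower, with a median of 0.24 (camera adjusted p = 0.0901). Ppard rose by 1.71 (SE 0.10) and Ppara fell with -1.67 (SE 0.18). LXR targets had 3 of 8 higher and 4 lower, with a median of -0.31, a mean of 0.13 and a test pointing down (camera adjusted p = 0.825). Sebaceous gland genes had 9 of 14 higher and 2 lower, with a median of 2.20 (camera adjusted p = 0.0356, adjusted p = 0.575 with an estimated correlation). Elovl3 rose by 4.07 (SE 0.33) and Acsbg1 fell with -1.48 (SE 0.08). The sebaceous call was lost without WT replicate 13 (adjusted p = 0.0562).

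Keratinocyte genes at 21 days moved in both directions. Hair follicle stem cell genes fell, with 9 of 10 lower and none higher (9 lower and 1 higher adjusted over the list alone) and a median of -1.77 (camera adjusted p = 0.000716, adjusted p = 0.494 with an estimated correlation). Krt15 went from 164700 ± 23100 to 12840 ± 2250 (-3.69, SE 0.15, limma adjusted p = 4.21e-08), and the growth factor gene Fgf18 had -4.26 (SE 0.21). Growing hair shaft genes had 3 of 9 higher and 5 lower, with a median of -1.31 (camera adjusted p = 0.277). Basal keratinocyte genes had 3 of 12 higher and 9 lower, with a median of -0.46 (camera adjusted p = 0.131). Krt14 rose by 2.09 (SE 0.14) while Col17a1, a hemidesmosome collagen, fell with -1.26 (SE 0.12). Suprabasal genes had 8 of 17 higher and 6 lower, with a median of 0.29, a mean of -0.10 and a test pointing up (camera adjusted p = 0.86). Krt77 went from 231700 ± 59700 to 4479 ± 1550 (-5.72, SE 0.26) and Krt1 from 49050 ± 4670 to 396400 ± 51900 (3.01, SE 0.14). Cornified envelope genes had 14 of 25 higher and 6 lower, with a median of 1.34 (camera adjusted p = 0.0476, adjusted p = 0.647 with an estimated correlation), among them the transglutaminase Tgm3 (5.92, SE 0.12) and Rptn (6.91, SE 0.19). That call was lost without WT replicate 13 (adjusted p = 0.0981) or 15 (adjusted p = 0.066), with the CPM filter (adjusted p = 0.0734) and in the fit of all 20 libraries (adjusted p = 0.0832).

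All 28 measured barrier stress genes were higher at 21 days, with a median of 9.04 (camera adjusted p = 5.71e-13, adjusted p = 0.494 with an estimated correlation), such as Krt16, from 1925 ± 965 to 241200 ± 15300 (7.11, SE 0.30, limma adjusted p = 5.93e-08). One of them, Sprr2k, was listed at 0 in every WT library. Sprr2b, Lce3b, Sprr2i, Sprr2k and Defb3 passed the filter only through their KO libraries, so for them a higher value in KO was fixed in advance. Inflammatory mediators had 18 of 19 higher and 1 lower, with a median of 3.40 (camera adjusted p = 6.43e-06, adjusted p = 0.21 with an estimated correlation), including the chemokines Cxcl1 (4.23, SE 0.18) and Cxcl2 (4.86, SE 0.25). Proliferation genes were all higher, 30 of 30, with a median of 2.15 (camera adjusted p = 5.71e-13, adjusted p = 0.421 with an estimated correlation), led by the replication gene Mcm5 (2.65, SE 0.09). Interferon response genes were lower, with 14 of 25 down and 1 up and a median of -1.07 (camera adjusted p = 0.00547, adjusted p = 0.494 with an estimated correlation). Usp18, which removes the ubiquitin-like protein Isg15, went from 319.2 ± 39.9 to 17.29 ± 2.8 (-4.13, SE 0.16, limma adjusted p = 4e-08), and the signalling gene Irf9 had -1.32 (SE 0.11). The one higher member, which the rule did not name, was Mx1 (1.09). The interferon call was lost in the fit of all 20 libraries (median -0.55, adjusted p = 0.0529), and its median was -0.57 without WT replicate 13, -0.63 without 15, -0.69 without 17 and -0.55 with no filter. For a member that passed the filter only through its WT libraries a lower value in KO was fixed in advance. Such a member left the fit where a WT library was left out. The size of the median of -1.07 thus depends on the filter.

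Energy and stress pathways rose at 21 days except for p53 targets. All 20 oxidative phosphorylation genes were higher, with a median of 1.06 (camera adjusted p = 4.77e-09, adjusted p = 0.421 with an estimated correlation), such as the ATP synthase gene Atp5b, from 11440 ± 655 to 30280 ± 567 (1.41, SE 0.07). Glycolysis genes had 14 of 18 higher and 1 lower, with a median of 1.21 (camera adjusted p = 0.000411), led by Gapdh (1.82, SE 0.09). Integrated stress response genes had 11 of 17 higher and 2 lower, with a median of 1.36 (camera adjusted p = 0.00332). The cystine transporter Slc7a11 rose by 7.62 (SE 0.28), while Atf3 fell with -1.68 (SE 0.22). ER chaperones had 12 of 14 higher and none lower, with a median of 0.62 (camera adjusted p = 0.00191). NRF2 targets had 15 of 17 higher and 2 lower, with a median of 1.07 (camera adjusted p = 0.000716), led by the aldo-keto reductase Akr1b8 (2.45, SE 0.10). These 4 lists each had adjusted p = 0.494 with an estimated correlation. Lysine acetyltransferases and deacetylases had 4 of 17 higher and 8 lower, with a median of -0.09 (camera adjusted p = 0.396). The p53 targets had 7 of 10 lower and 1 higher, with a median of -0.41 (camera adjusted p = 0.0477, adjusted p = 0.494 with an estimated correlation), led by Trp53inp1 (-2.02, SE 0.20) and Bbc3 (-2.55, SE 0.27). That call was lost in the fit of all 20 libraries (adjusted p = 0.0753) and without WT replicate 17 (adjusted p = 0.0621) or KO replicate 14 (adjusted p = 0.0633), 16 (adjusted p = 0.0575) or 18 (adjusted p = 0.0676).

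Markers of other cell types also moved at 21 days. T cell genes fell, with 8 of 11 lower and a median of -1.12 (camera adjusted p = 0.0192, adjusted p = 0.494 with an estimated correlation), led by Nkg7 (-2.30, SE 0.29). Scaling to equal totals (adjusted p = 0.0544) and the CPM filter (adjusted p = 0.0958) ended that call. Dermal fibroblast genes had 6 of 7 lower and a median of -2.18 (camera adjusted p = 0.0476, adjusted p = 0.494 with an estimated correlation), with Col3a1 at 67.33 ± 51.8 in WT and 3.273 ± 1.54 in KO (-3.75, SE 0.53). That call was lost under total scaling (adjusted p = 0.0894) and in the fit of all 20 libraries (adjusted p = 0.0832). It was also lost without KO replicate 14 (0.0511), 16 (0.0534) or 18 (0.0653), and without WT replicate 13 (0.227), 15 (0.187), 17 (0.249, median -1.31) or 19 (0.156). Col3a1 and Dcn passed the filter only through their WT libraries, so for them a lower value in KO was fixed in advance. They were tested in only 4 of the 8 runs, since the filter took them out where a WT library was left out. The losses without a WT library thus rest on fewer members. Macrophage genes had 6 of 8 higher and 1 lower (median 1.59, camera adjusted p = 0.117), endothelial genes 3 of 4 higher and 1 lower (median 1.82, camera adjusted p = 0.317) and melanocyte genes 2 of 3 higher (median 0.84, camera adjusted p = 0.344). Langerhans and dendritic cell genes had 1 of 9 higher and 3 lower (median -0.08, camera adjusted p = 0.383), and Schwann cell genes 1 of 3 lower (median -0.87, camera adjusted p = 0.249). Neutrophil genes had 1 higher and 1 lower of 3, with a median of -0.54, a mean of 1.34 and a test pointing down (camera adjusted p = 0.825). The higher one was Cxcr2, from 12.11 ± 9.49 to 816.2 ± 44.9 (6.44, SE 0.63). Adipocyte, muscle, mast cell and red blood cell lists had fewer than 3 measured members.

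**Figure D2:**
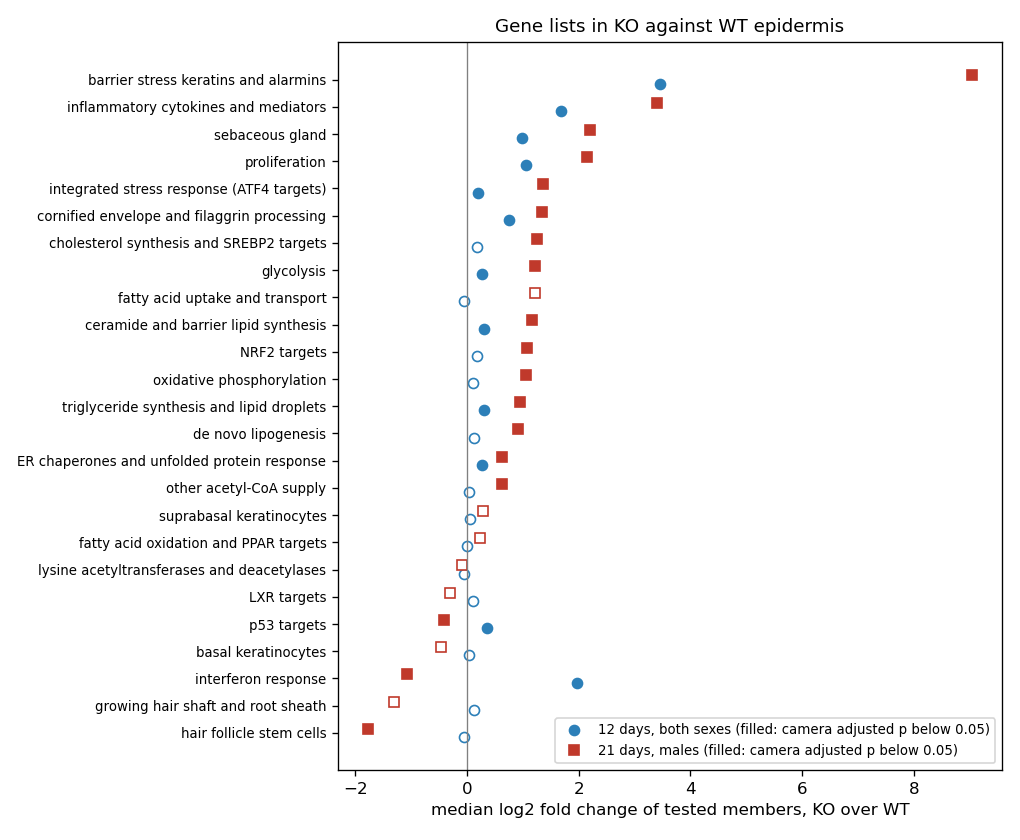
Median log2 fold change, KO over WT, of the tested members of 25 gene lists at 12 days (circles, both sexes) and 21 days (squares, males), with filled symbols for a camera adjusted p below 0.05 at the preset correlation. The interferon list lies at 1.97 at 12 days and at -1.07 at 21 days (-0.55 with no filter), and the barrier stress list at 3.45 and 9.04. With equal totals all 21 day values are lower by about 0.22.

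The difference between the 21 day and 12 day responses in males was tested directly. Interferon genes had 26 of 29 members lower in the difference (28 adjusted over the list alone) and a median of -2.96 (camera adjusted p = 2.4e-12). The difference holds the rise at 12 days as well as the fall at 21 days, and not every member fell at 21 days. Hair follicle stem cell genes (8 of 10 lower, median -1.74, camera adjusted p = 1.35e-05) and p53 targets (9 of 10 lower, median -0.74, camera adjusted p = 0.000552) were also lower in the difference, and oxidative phosphorylation genes higher (19 of 20, or 20 adjusted over the list alone, median 0.89, camera adjusted p = 1.1e-10). Cholesterol synthesis genes had 15 of 25 higher (19 adjusted over the list alone, median 1.05, camera adjusted p = 5.53e-06), ceramide genes 12 of 26 (median 0.80, camera adjusted p = 0.000445) and barrier stress genes 10 of 28 (12 adjusted over the list alone, median 3.44, camera adjusted p = 9.66e-05). In all 19 of 35 lists passed, none of them with an estimated correlation (smallest adjusted p = 0.0987). Without KO male 2 of 12 days 15 of the 19 still passed, and de novo lipogenesis (adjusted p = 0.0816), triglyceride (adjusted p = 0.15), fatty acid oxidation (adjusted p = 0.169) and sebaceous gland genes (adjusted p = 0.15) no longer did. The median differences of inflammatory mediators and proliferation genes were 1.09 and 0.74 with that library and 1.90 and 1.22 without it, and that of barrier stress genes 5.09 without it (adjusted p = 3.98e-12). In the runs without each of the 14 libraries 11 of the 19 calls always held. Inflammatory mediators were lost in 4 runs (adjusted p up to 0.0754), ER chaperones (0.34, camera adjusted p = 0.0463) in 8 (adjusted p up to 0.128), sebaceous gland genes (1.24) in 7 and triglyceride genes (0.62) in 7 (both adjusted p up to 0.15), T cell genes (-1.19) without WT male 11 (-0.73, adjusted p = 0.0604) and the integrated stress response (0.96) without KO replicate 20 (adjusted p = 0.05). With fry the barrier stress (adjusted p = 0.0797), inflammatory (adjusted p = 0.0754), proliferation (adjusted p = 0.0884), sebaceous gland (adjusted p = 0.0772), ER chaperone (adjusted p = 0.0927), glycolysis (adjusted p = 0.0683) and T cell calls (adjusted p = 0.0557) ended.

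Over all genes 5107 of 14257 differed in their response between the days, 2453 higher and 2654 lower. The 5 with the smallest p fell at 21 days. Fn1, fibronectin, was at 484.8 ± 22 and 649.7 ± 53.2 in WT and KO males at 12 days (SD, n = 3 each) and went from 763 ± 53.8 to 98.15 ± 21 at 21 days, a difference between the days of -3.38 (SE 0.19, limma adjusted p = 6.82e-07). Arhgef28 had a difference of -3.57 (SE 0.19), Ralgps1 -3.27 (SE 0.19) and Bmper, which binds bone morphogenetic proteins, -4.71 (SE 0.28). Mitf, a transcription factor of melanocytes, had -2.61 (SE 0.16, limma adjusted p = 8.81e-07), from 978.7 ± 84.2 to 160 ± 17.8 at 21 days. Acss2 differed by 1.41 and Acly by 0.75, the latter call being lost without WT male 11 (0.61, adjusted p = 0.0569), KO male 5 (0.66, adjusted p = 0.0583) or KO male 12 (0.72, adjusted p = 0.0515). With equal totals 4908 genes passed, 1294 higher and 3614 lower (26.4% against 48% higher), and with array weights 7887. The days are separate tables normalised apart, so levels set beside each other across them also carry that difference, and a batch shared by a whole day cancels only where it acted alike on both genotypes.

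Most genes called at 12 days changed the same way at 21 days. Of 457 genes higher at 12 days in both sexes and tested on both days, 323 were higher at 21 days, where independent lists would share 159 (Fisher's exact test, odds ratio 4.76, p = 1.74e-56), and 57 were lower. Of 313 lower genes 253 were lower at 21 days against 110 for independent lists (Fisher's exact test, odds ratio 8.18, p = 2.86e-63), and 17 were higher. From the male fit of 12 days 97 of 131 higher and 35 of 38 lower genes were shared. The days have no library in common. Across 13354 genes the fold changes of the days had r = 0.57 and rho = 0.466. Some interferon genes were among those that turned. Examples outside the rule for naming, picked after their values were seen, were Isg15 (2.32 at 12 days and -1.99 at 21 days), Ifit1 (3.66 and -1.50) and Irf7 (1.40 and -1.13).

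**Figure D3:**
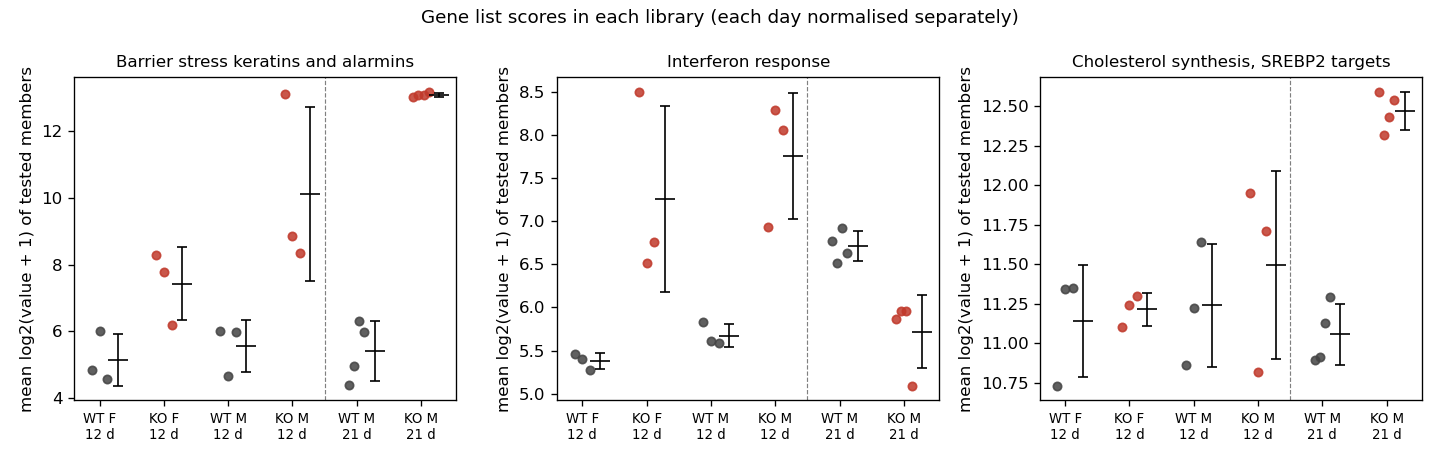
Score of 3 gene lists (mean log2(value + 1) of the tested members, vertical axes not starting at 0) in each library by genotype, sex and day, with the group mean and SD (n = 3 per group at 12 days, 4 at 21 days). KO male 2 has a barrier stress score of 13.11, beside 13.03 to 13.18 in the KO libraries of 21 days. The interferon scores of KO lie at 6.521 to 8.504 at 12 days and 5.091 to 5.964 at 21 days. The days were normalised separately and had different tested members (barrier stress 23 and 28, interferon 31 and 25), so these scores cannot be compared between days.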

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

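The tests of the CreERT2 transgene, of immune cells, of a 21 day library under a 12 day label and of a few abundant genes, and the mean without KO male 2 for the other KO libraries, were chosen only after the results were seen.

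Esr1 was higher in every KO library of both days, with the lowest KO library at 414.4 and the highest WT library at 39.55. CreERT2 carries a part of an estrogen receptor gene, so reads of the transgene could have been counted as Esr1. The fold of such reads would stay level while the response grew. In males the fold of Esr1 differed between the days by -0.88 (SE 0.48, limma adjusted p = 0.173). Of the 18 genes that rose by at least 4 on the log2 scale at 12 days, Gypc (0.12, SE 0.73), Gm8615 (0.56, SE 0.88) and Nppb (0.74, SE 1.19) had differences as small. Their SEs are wide, and for Nppb the lowest KO library (4.45) lay below the highest WT library (7.887). Whether these genes are level or follow the response is not shown, so the test does not single out the transgene. A rise of the Esr1 gene with the response would raise it with the barrier stress score, and over the 6 KO libraries of 12 days the Spearman rho was 0.771 (exact p = 0.103, adjusted p = 0.206; Pearson r 0.538, exact p = 0.235, and 0.624 without the 2 farthest libraries), short of the 0.8 set for it, so the explanations cannot be told apart from 6 libraries. The transgene's sequence and the genotype of the WT mice for it are not given in the sources used here.

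Interferon response genes were higher in KO at 12 days, with a median of 1.97. Admixed T cells, Langerhans and dendritic cells, or macrophages as the source are argued against by their markers, whose highest median was 0.14. Neutrophils are not covered by this. Their list had 3 measured members and a median of -0.33, but Cxcr2 was higher (2.66 without KO male 2, limma adjusted p = 0.0218). KO male 2 as the source is argued against by the median of 2.00 without that library. That the genes answer the loss of Acly and Acss2 in the epidermis itself, or tamoxifen in mice that carry Cre, stays open as a hypothesis and was not tested.

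KO male 2 of 12 days stood apart, at 77.8 on the first principal component where the next library lay at 29.6. Its barrier stress score was 13.11 over 23 members. The 21 day KO libraries had 13.03 to 13.18, in a table normalised apart and over 28 members, so these scores cannot be compared directly. A 21 day KO library under a 12 day label is argued against by the 10 genes with the largest falls at 21 days, whose mean log2 value in this library was 8.64, which is 4.56 above the highest of the 21 day KO libraries (3.55 to 4.08) and nearer to the other KO libraries of 12 days (10.27 to 10.77), and against the WT males of its own table it lay at -2.19 where the 21 day KO libraries lay at -6.98 to -6.46. A few genes taking most of the reads are argued against by the share of its 10 highest genes, 9.06%, within the 8.07 to 9.33% of the other KO libraries. Its deviation from the other KO libraries of 12 days had a Pearson r of 0.582 with the 21 day fold change across genes, where each of the other 5 had -0.208 to 0.140 against a mean without KO male 2, which goes with a library further along the response seen at 21 days. What made 1 mouse differ stays open.

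In splits of the same libraries only the real one gave as many genes at 12 days in both sexes (815 genes, highest other split 32) and at 21 days (9557, highest other 1). The shares, 1 of 100 and 1 of 35, argue against chance, though 1 of 35 is the smallest share possible at 21 days. For the difference between days (5107, highest other 1) the other splits mix 2 tables normalised apart. A day effect then widens their spread, so these splits cannot gauge chance. For the difference between sexes 3 of 100 splits gave the 1 gene of the real one (highest other 1), a share under 0.05, but other splits equal the count, vooma gave 0, and the reads of the gene, Mfrp, are uncertain. For females (93, highest other 1) and males (180, highest other 2) the 10 splits are too few for a share under 0.05.

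Of 150 tests for a library far from its group 17 were met, where chance gives 7.5, and 5 of the 17 were in KO male 2. These 5 were Acly at 4136 (nearest library 3384) and the scores of integrated stress response at 9.725 (9.273), NRF2 targets at 9.68 (9.201), oxidative phosphorylation at 11.43 (11.03) and skeletal muscle at 4.675 (4.242). KO male 12 had a total of values of 21.65 M (nearest 20.67 M), a triglyceride score of 9.68 (9.403) and a Langerhans and dendritic cell score of 9.101 (9.587). At 21 days WT replicate 13 had a fatty acid oxidation score of 8.662 (8.839), and KO replicate 14 had 28.4 M estimated reads (23.2 M). KO replicate 18 had Acly at 3805 (5255), a fatty acid uptake score of 9.185 (9.29) and a cornified envelope score of 12.33 (12.89). KO replicate 20 had scores of 8.247 for inflammatory mediators (8.612), 5.091 for interferon response (5.862), 5.395 for melanocytes (6.19) and 5.453 for macrophages (6.242).

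The response of these differed between the sexes by the test of the difference, with the median or log2 difference (males less females) of -0.30 for sebaceous gland, 2.31 for barrier stress, 0.55 for inflammatory mediators, 0.90 for proliferation, 0.19 for integrated stress response, 0.37 for glycolysis, 0.13 for oxidative phosphorylation and 7.36 for Mfrp. Without KO male 2 the calls of barrier stress (adjusted p = 0.116), sebaceous gland (adjusted p = 0.136), integrated stress response (adjusted p = 0.217) and oxidative phosphorylation (adjusted p = 0.633) ended. Mfrp was 0 in 3 WT males of 12 days and ranged from 0 to 224.1 in WT males of 21 days.

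The response of these differed between the days in males, with the median or log2 difference (21 days less 12 days). Lower were interferon response (-2.96), hair follicle stem cells (-1.74), T cells (-1.19) and p53 targets (-0.74), and the genes Arhgef28 (-3.57), Fn1 (-3.38), Ralgps1 (-3.27), Bmper (-4.71) and Mitf (-2.61). Higher were barrier stress (3.44), inflammatory mediators (1.09), proliferation (0.74), cholesterol synthesis (1.05), ceramide (0.80), de novo lipogenesis (0.78), triglyceride (0.62), fatty acid oxidation (0.29), sebaceous gland (1.24) and other acetyl-CoA supply (0.51). Also higher were integrated stress response (0.96), ER chaperones (0.34), NRF2 targets (1.15), glycolysis (0.71) and oxidative phosphorylation (0.89), and Acly (0.75) and Acss2 (1.41). No list of the differences between sexes or days passed with an estimated correlation. Without KO male 2 of 12 days de novo lipogenesis (adjusted p = 0.0816), triglyceride (adjusted p = 0.15), fatty acid oxidation (adjusted p = 0.169) and sebaceous gland (adjusted p = 0.15) lost the call between days, and inflammatory mediators had 1.90 and proliferation 1.22. Acly lost it without WT male 11 (adjusted p = 0.0569), KO male 5 (adjusted p = 0.0583) or KO male 12 (adjusted p = 0.0515).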

How the results depend on the processing

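The settings with TMM, pseudocounts of 0.5 and 5, vooma weights, array weights and no trend were chosen after the values were seen. For the lists this held for every setting but the estimated correlation, fry and the runs without 1 library. Under the settings run no called gene or list that the text names turned its direction, apart from oxidative phosphorylation between sexes without KO male 2 (median -0.01). Directions of lists were not compared for the estimated correlation and fry, so those settings are not covered. Counts that stayed within 1.5 times of the reported ones ranged from 666 to 815 at 12 days in both sexes and from 7714 to 10555 at 21 days over the other settings, the runs without 1 library aside. Scaling by median of ratios moved neither count, which the authors' own scaling makes a setting without effect.

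With a mean CPM of at least 5, 504 genes were called at 12 days in both sexes, 40 in females and 76 in males. Array weights gave 2259, 883 and 778, and 7887 for the difference between days. The estimate of these weights stopped before its tolerance was reached in females, in males, between sexes and between days. Vooma gave 50 in females, 90 in males and 0 for the difference between sexes. Tested against a fold of 1.5, 93 genes passed at 12 days in both sexes and 4051 at 21 days, while Acly at 21 days (adjusted p = 0.536) and Acss2 at 12 days (adjusted p = 0.115) did not. A fit of all 20 libraries gave 1382 at 12 days, the 6 female libraries alone 190 and the 6 male libraries alone 22, where fewer or more libraries set the spread. With an estimated correlation 0 lists passed at 12 days (smallest adjusted p = 0.19) and 0 at 21 days (smallest adjusted p = 0.21), against 12 and 20, while fry passed 10 and 28. At 21 days 8 of the lists that fry passed had not passed camera, among them fatty acid uptake, fatty acid oxidation and growing hair shaft genes. Scaled to equal totals, the medians of 21 days were 0.40 for other acetyl-CoA supply, 0.40 for ER chaperones and -0.63 for p53 targets. Fatty acid oxidation genes also passed camera with no filter (adjusted p = 0.0448). Fry passed 0 lists in females, 1 in males, 0 between sexes and 16 between days, against 10, 13, 7 and 19 with camera. Calls shared by the days in the higher direction were 99 at adjusted p 0.01 and 160 with the CPM filter in both sexes (21 and 39 from males), and in the lower direction 61 at adjusted p 0.01 (2 from males, 16 with the CPM filter). The cause was not tested unless the setting itself holds fewer genes or libraries.

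Without 1 library the counts ranged from 449 to 894 at 12 days in both sexes, 16 to 142 in females, 38 to 289 in males, 1 to 2 between sexes, 8786 to 9231 at 21 days and 3966 to 5847 between days. The ends were without WT female 9 (449) and KO male 2 (894), WT female 9 (16) and KO male 2 (142), and WT male 6 (38) and KO male 5 (289). Without WT male 3 or KO male 12 the count between sexes was 2. Lists passing numbered 12 to 16 at 12 days in both sexes, 8 to 12 in females, 11 to 18 in males, 4 to 11 between sexes, 17 to 20 at 21 days and 15 to 20 between days. Of 69 called genes drawn for naming at 12 days 43 kept the call in all 12 such runs and 26 lost it in at least 1 (adjusted p up to 0.118). At 21 days 157 of 159 kept it in every run that tested them. Some of these, such as Mrgprb2, Gabrp, Pyy and Sprr2b, passed the filter in only 4 of the 8 runs.

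DESeq2's Wald test, limma-voom and a surrogate variable were planned and not run, since they need counts. No paired analysis was possible because no replicate number is shared by 2 groups. Estimated depth of 13.4 to 28.4 M reads limits genes of low value, and 5065 genes at 12 days and 5661 at 21 days were 0 in all libraries.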

Other observations

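The gene families and genes here were chosen after their values were seen, so their counts are not independent evidence.

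Several families outside the lists moved together at 21 days. All 5 stefin A genes, inhibitors of cysteine proteases, were higher, with a median of 9.07, and Stfa3 went from 168 ± 96.6 to 57200 ± 9710 (SD, n = 4 each). All 4 Serpinb3 genes were higher (median 5.06), as were 9 of 10 kallikreins (median 2.31) and 4 of 5 interleukin 1 family genes with 1 lower (median 3.74). At 12 days 3 of 5 stefin A genes (median 4.18), 3 of 10 kallikreins (median 0.84) and 2 of 5 interleukin 1 family genes (median 1.24) were higher, and none of 2 Serpinb3 genes passed (median 1.23). Copies within the stefin A and Serpinb3 families are close, so their reads are uncertain. The gap junction genes Gjb2, from 315 ± 117 to 22100 ± 3460 (6.19, SE 0.24), and Gjb6 (5.52, SE 0.12) rose at 21 days. The lipoxygenase gene Alox8 rose at both days, by 3.02 (SE 0.58, limma adjusted p = 0.0104) and 7.24 (SE 0.21, limma adjusted p = 8.56e-09), and Cyp7b1, which hydroxylates oxysterols, went from 1.34 ± 0.539 to 830 ± 18.1 at 21 days (SE 0.19 on the log2 scale).

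Families that fell at 21 days were the Skint genes, known from the selection of epidermal T cells (9 of 11 lower, 1 higher, median -1.68), Wnt ligands (13 of 14 lower, median -1.89), type IV collagens of the basement membrane (6 of 6, median -2.01), circadian clock output genes (10 of 10, median -1.47), immediate early genes (8 of 9, median -0.89) and both Mrgprb receptors (median -7.30). The Mrgprb receptors passed the filter of 21 days only through their WT libraries, so a lower value in KO was fixed in advance. At 12 days 1 of 11 Skint genes, 1 of 13 Wnt ligands, 2 of 6 type IV collagens and 1 of 10 clock output genes were lower, and none of 9 immediate early genes or 2 Mrgprb receptors passed. Skint7 fell at both days, from 1710 ± 228 to 691 ± 206 (SD, n = 6 each; -1.36, SE 0.19) and from 1390 ± 190 to 40.8 ± 8.44 (SD, n = 4 each; -5.07, SE 0.16). Genes of protein turnover were mostly higher at 21 days, with 33 of 37 proteasome genes (2 lower, median 0.74), 66 of 75 mitochondrial ribosomal genes (median 0.73) and 64 of 75 cytosolic ribosomal genes (1 lower, median 0.43). With equal totals these were 29 (3 lower, 0.53), 58 (2 lower, 0.51) and 44 (5 lower, 0.22), where the median of all genes was -0.21. At 12 days 3 of 37, 1 of 75 and none of 75 were higher.

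Krt7, a keratin of simple epithelia, rose at 12 days by 2.30 (SE 0.22, limma adjusted p = 0.000122) and fell at 21 days with -1.03 (SE 0.27, limma adjusted p = 0.00675), a difference in males of -3.20 (SE 0.43). Gria3, a glutamate receptor subunit, was at 42.99 to 94.87 in the KO libraries of 12 days and 0 to 1.778 in WT (5.19, SE 0.34, limma adjusted p = 9.32e-06), and at 0.9377 to 2.846 in the KO libraries of 21 days and 1.082 to 17.61 in WT. Its difference between the days was -6.76 (SE 0.95, limma adjusted p = 0.000251). Gypc, a membrane protein of red blood cells, had a mean CPM too low for the rule of named genes and rose by 6.14 at 12 days (SE 0.36, limma adjusted p = 4.76e-06), from 1.857 ± 1.59 to 176 ± 28.8 (SD, n = 6 each), and by 5.98 at 21 days (SE 0.50).

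Fold changes had a Spearman rho with transcript length across genes of -0.074 at 12 days and -0.110 at 21 days, where the shortest 20% of genes had a median of 0.14 and the longest 20% -0.14. At 21 days the first principal component held 84.7% of the variance and split the genotypes. Correlations between libraries were 0.9783 to 0.9896 within a genotype and 0.8307 to 0.8674 between genotypes at 21 days. At 12 days they were 0.9477 to 0.9863 within the groups of genotype and sex and 0.9118 to 0.9852 between them, which overlap.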
